A study of Mus musculus with 12 samples.

How the data were processed

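Messenger RNA libraries of 12 samples of the mouse line J774A.1 were analysed, in 4 groups of 3 as the labels name them: cell media, HBSS, HOCl at 20 µM and HOCl at 100 µM. Exposure lasted 1 h and was followed by 24 h in full medium. The deposited table held FPKM values for 28977 gene IDs in the 12 libraries. Per the submitters' processing notes, HISAT2 and featureCounts were used with the GRCm39 mouse build, and their versions and settings, strand included, were not given in the sources used here. The labels name 2 sequencing instruments for the series without saying which library ran on which, so no batch by instrument could be tested.

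No counts were given. In each library the values below 1 FPKM, multiplied by exon length, lay on multiples of a single step, taken as 1 read or fragment. The step gave the number of reads that the values of a library were divided by, between 17683937 and 21408518, and with it 98.26% of values below 1 were whole numbers of reads within 0.01, where chance gives 2%. The reads so recovered served for depth and for 1 alternative test only.

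Gene symbols, exon lengths and GC content came from the GENCODE M21 annotation, which is of another build than the notes name, so it was used for names and sequence properties only and no coordinates are given. Of the 28977 IDs, 28302 had a symbol. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were kept, which left 12026, of which 11895 (98.91%) had a symbol, a length and a GC content. Values were taken as log2(FPKM + 1). Genes with near-identical copies, among them ribosomal protein, histone and Oas genes, may share reads with these copies, and their values are less certain.

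Each comparison was tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 libraries in one model for a shared estimate of spread, a mean-variance trend and no other covariate. The tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12026 genes. With 3 libraries against 3, a permutation of 1 value could not give a p below 0.1, so single values were not tested that way. The 4 comparisons were 20 µM with HBSS, 100 µM with HBSS, 100 µM with 20 µM, and HBSS with cell media.

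Before the data were examined, 34 gene lists, a panel of 25 genes, the tests, the rule for naming genes and most alternatives were fixed. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 5 kept genes, and beside it with camera's estimated correlation and with fry. Lists of markers of other cell types had at most 2 kept genes and were not tested as lists. The median log2 difference of a list's kept members is its value. Named genes were: the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 FPKM and groups that did not overlap, which gave Ddit3 in HBSS against cell media alone; up to 4 members with the smallest adjusted p in each list described; and the panel in the comparisons of HOCl with HBSS. Long parts were shortened from the end of that order, and any other gene is said to have been chosen after its values were seen.

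Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a model of the 2 groups compared, the replicate number as a block, no mean-variance trend, library weights, cell media as the control, a minimum log2 difference of 1, and leaving out each library. After the data were seen, quantile normalization was extended from the counts and the mitophagy core to all lists called, and 4 more were added: leaving out cell media replicates 1 and 2, limma-voom on the recovered reads of 11895 genes, and the removal of each library's loess trend (span 0.5) on exon length or on GC content. Overlap between the doses was compared with simulated unchanged groups against the same controls.

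The limma step was tested on simulated data made from the 100 µM and HBSS comparison, with 12026 genes, 5 rounds and 200 changed genes in each. With 12 libraries it recovered 10.8% of genes changed 1.25-fold, 52.8% of those changed 1.5-fold, 84% of those changed 2-fold and 96.8% of those changed 4-fold, and called 0.02% of unchanged genes. With 10 libraries it recovered 41.2%, 75.6%, 92.8% and 97.2%, and called 0.08%. A list shifted by 0.2 was called by camera in 5 of 5 rounds, and other lists in 3 of 150 tests with 12 libraries and 4 of 150 with 10. The simulated genes varied independently of each other, so these rates do not hold for lists whose members vary together. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out, and 675 IDs without a symbol were kept under their IDs.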

Results

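J774A.1 cells, a mouse macrophage-like line, were sequenced as mRNA libraries 24 h after a 1 h exposure to hypochlorous acid (HOCl), the oxidant that the enzyme myeloperoxidase makes from hydrogen peroxide and chloride. The 12 libraries fell into 4 groups of 3: untreated cells kept in cell media, cells given the salt solution HBSS alone (0 µM HOCl, the vehicle control), cells given HOCl at 20 µM in HBSS and cells given HOCl at 100 µM in HBSS. The title of the series is about mitophagy genes, those for the removal of mitochondria by autophagy, being raised by HOCl. The study used lethal and sublethal doses, and the labels do not say which dose is which. The FPKM values of each library rested on between 17683937 and 21408518 reads. Nothing in the labels says that the replicates were separate cultures, so all p-values measure only the spread between these samples. Values are given as mean FPKM ± SD with n = 3 in each group, and differences on the log2 scale of FPKM plus a pseudocount of 1.

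Cell media replicates 1 and 2 stood apart from the other 10 libraries. They correlated at 0.988 with each other and at 0.946 to 0.971 with the others, among which the lowest correlation was 0.974. Transcripts of the cytosolic ribosomal proteins made up 12.22% and 11.96% of the FPKM of these 2 libraries and 7.01% to 7.85% in the other 10. Rplp1, a protein of the ribosomal stalk, stood at 5281 and 4479 FPKM against 1274 to 1623, and Lars2, the mitochondrial leucyl-tRNA synthetase, at 295 and 48.7 FPKM against 14.8 to 20.9. The ID farthest above the other libraries, ENSMUSG00000119584, which had no symbol, stood at 16232 and 1541 FPKM against 321 to 705. Small RNA genes were among the lowest, with Snord110 at 0 and 0.83 FPKM against 3.92 to 13.8. These genes were chosen after their values were seen. In both libraries, 95 genes stood at least 2 times above the highest of the other 10, and 178 stood under 50% of the lowest. The mitochondrially encoded genes made up 5.49% and 6.45% of the FPKM in cell media replicates 1 and 2 and 7.96% in replicate 3. They made up 8.26 ± 0.57% in HBSS, 7.33 ± 0.06% at 20 µM and 7.38 ± 0.52% at 100 µM. The spread of all groups was estimated together. The count of genes called over all genes in each comparison is therefore also given without cell media replicates 1 and 2, on 10 libraries. This choice was made after the data were seen. For HBSS against cell media the 10 libraries leave cell media replicate 3 alone (n = 1), with the spread taken from the other groups, so those values hold for that library only.

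**Figure D1:**
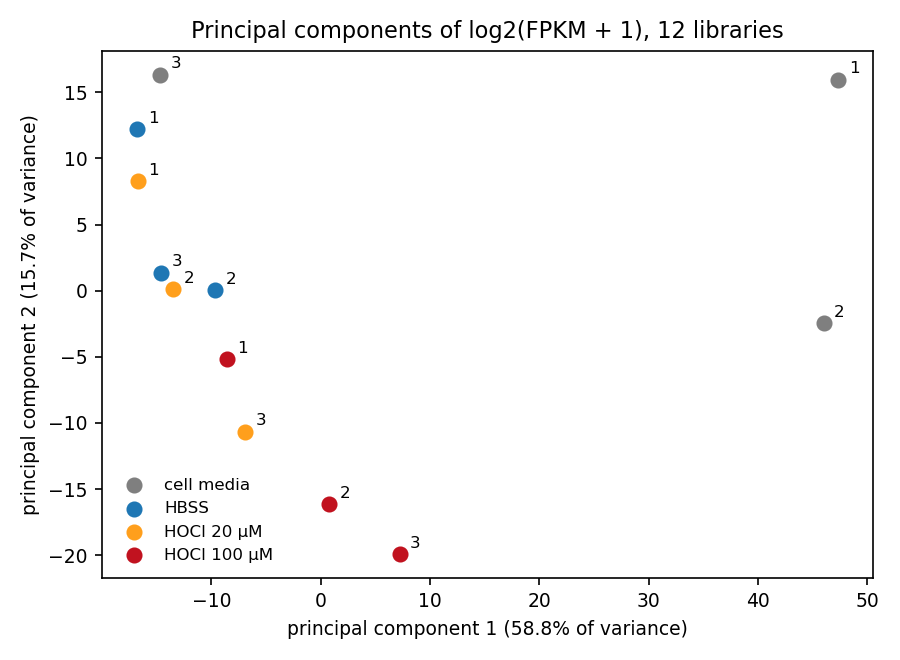
Principal components of log2(FPKM + 1) for the 12 libraries, with component 1 (58.8% of the variance) on the horizontal axis and component 2 (15.7%) on the vertical axis. Points are libraries, coloured by group and numbered by replicate, and cell media replicates 1 and 2 lie far to the right of the other 10.

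The comparison of 20 µM HOCl with HBSS asks whether the lower dose moved mitophagy genes relative to the vehicle control. Mitophagy genes at 20 µM stood close to their HBSS levels. Pink1, the kinase that accumulates on damaged mitochondria, was at 4.78 ± 0.94 FPKM in HBSS and 4.41 ± 0.27 at 20 µM (log2 difference −0.085, SE 0.13). The receptors that tie the mitochondrial outer membrane to autophagosomes gave 14.9 ± 2.4 and 14.2 ± 1.3 for Bnip3, 24.4 ± 2.5 and 23.4 ± 2.0 for Bnip3l, and 7.62 ± 0.47 and 7.04 ± 0.06 for Fundc1. Sqstm1, the adaptor p62 that links ubiquitin to LC3, was at 183 ± 26 and 186 ± 19. Of the 38 measured members of the mitophagy core list, 23 were higher and 15 lower, with a median log2 difference of 0.0081, which was −0.0031 with median-of-ratios scaling, −0.0044 with quantile normalization and −0.0016 without HOCl 20 µM replicate 1. The camera test of limma gave this list an adjusted p = 0.973, and an adjusted p = 0.976 with an estimated correlation. Its members with the smallest p included Usp30, a deubiquitinase that opposes mitophagy (2.08 ± 0.16 and 2.36 ± 0.25), and Ulk1, the kinase that starts autophagosome formation (2.54 ± 0.09 and 2.76 ± 0.18). Mitophagy regulators outside the core had a median of 0.011, −0.0007 with median-of-ratios scaling, with 19 of 33 higher (camera, adjusted p = 0.682).

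Interferon-stimulated genes were the 1 list of 31 that camera called at 20 µM, with 20 of 29 members lower and a median log2 difference of −0.074 (limma's camera, adjusted p = 4.26e-05, and adjusted p = 0.976 with an estimated correlation). Oas1g, a sensor of double-stranded RNA, stood at 25.9 ± 1.4 FPKM in HBSS and 22.4 ± 0.7 at 20 µM, and Ifi44 at 5.00 ± 0.14 and 3.89 ± 0.28. The call rested on a single library: without HOCl 20 µM replicate 1 the median was −0.026 (camera, adjusted p = 0.459, within a range of 1.83e-12 to 0.459 over the alternatives). NRF2 targets, the genes of the main antioxidant transcription factor, were not called, with 21 of 27 higher, a median of 0.040 and a camera adjusted p = 0.0763. Osgin1, a target of NRF2 that responds to oxidative stress, stood at 4.96 ± 0.80 and 6.62 ± 0.88 FPKM. The medians of the 30 lists not called ranged from −0.14 to 0.099, the lowest of them that of the mitochondrially encoded genes, of which 10 of 13 were lower (mean −0.012, and a median of −0.029 with quantile normalization). On the 10 libraries camera called 3 lists: interferon-stimulated genes, NRF2 targets and mitochondrially encoded genes, each at an adjusted p = 0.947 with an estimated correlation. No single gene passed: limma called 0 of 12026 genes, limma-voom called 0, and limma on the 10 libraries called 0. At an unadjusted p under 0.05 limma on all 12 libraries had 130 genes. Uniform p-values would give 601, and other splits of these 6 libraries gave 44 to 379. The spread of this fit includes cell media replicates 1 and 2, so its p-values need not be uniform. Of the panel of 25 genes fixed beforehand, 21 were measured and 0 were called. Their log2 differences ran from −0.10 to 0.11, and the 95% confidence intervals reached from −0.57 to 0.56. Leaving out 1 library turned the direction of 13 of the 21. Of those given above, Pink1 was 0.045 without HBSS replicate 1, Bnip3 0.061 without HBSS replicate 1 and 0.0040 without HOCl 20 µM replicate 3, Bnip3l 0.022 and 0.011 without the same libraries, and Sqstm1 −0.066 without HBSS replicate 3 and −0.043 without HOCl 20 µM replicate 1.

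The comparison of 100 µM HOCl with HBSS puts the same question at the higher dose. Mitophagy genes did not move as a group at 100 µM, and the members that differed most went both ways. Map1lc3b, the LC3 protein that coats autophagosomes, stood at 8.56 ± 0.36 FPKM in HBSS and 9.87 ± 0.15 at 100 µM (log2 difference 0.19, SE 0.12), and Nipsnap1, which marks damaged mitochondria for autophagy, at 14.4 ± 0.4 and 16.3 ± 0.6. Rhot2, a mitochondrial transport GTPase, was at 3.75 ± 0.21 and 3.34 ± 0.04, and Tbc1d17, a Rab GTPase-activating protein, at 2.82 ± 0.30 and 2.39 ± 0.13. Pink1 gave 4.78 ± 0.94 and 5.42 ± 0.43 (log2 difference 0.16, SE 0.13, 0.29 without HBSS replicate 1 and 0.084 without HBSS replicate 3), Bnip3 14.9 ± 2.4 and 15.9 ± 1.4, Bnip3l 24.4 ± 2.5 and 23.1 ± 0.5, Fundc1 7.62 ± 0.47 and 7.75 ± 0.88, and Sqstm1 183 ± 26 and 166 ± 11. None of these genes passed on all 12 libraries, with limma adjusted p values from 0.665 for Rhot2 to 0.95 for Fundc1. That fit's spread includes cell media replicates 1 and 2, and its median standard error was 0.132 against 0.073 on the 10 libraries. Over the alternatives, the genes' lowest limma adjusted p ran from 0.0721 for Map1lc3b to 0.813 for Fundc1, and none was called. With 1 library left out, the log2 difference of Bnip3 ranged from 0.034 to 0.22 and that of Sqstm1 from −0.22 to −0.022. The core list had 20 members higher and 18 lower and a median log2 difference of 0.015 (limma's camera, adjusted p = 0.663, and adjusted p = 0.887 with an estimated correlation). With all 12 libraries in the fit, 0 of the 38 passed over all genes or adjusted over the list alone. The sign of the median turned with quantile normalization (−0.0040) and without HBSS replicate 3 (−0.016), and that of Bnip3l without HBSS replicate 1 (0.0085) and of Fundc1 without HBSS replicate 3 (−0.027) and without HOCl 100 µM replicate 2 (−0.055).

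Regulators of mitophagy outside the core had a median of −0.012 at 100 µM, which was 0.018 with median-of-ratios scaling, with 14 of 33 higher, and the autophagy machinery a median of −0.036 with 15 of 39 higher (camera, adjusted p = 0.807 and 0.648). Jun, a subunit of the transcription factor AP-1, stood at 32.2 ± 3.7 and 26.2 ± 0.6 FPKM, and Tfeb, the regulator of lysosome and autophagy genes, at 2.11 ± 0.08 and 2.62 ± 0.22. Wdfy3, a scaffold for the autophagy of protein aggregates, was at 11.8 ± 1.0 and 7.89 ± 1.78 (log2 difference −0.54, SE 0.21). Of the panel of 25 genes, 21 were measured and 0 were called, with 3 at an unadjusted p under 0.05, and the 95% confidence intervals reached from −0.89 to 0.74. On the 10 libraries limma gave 8 of them an unadjusted p under 0.05 and called 0. The panel gene farthest from HBSS was Ddit3, the stress factor CHOP, at 24.4 ± 2.0 and 15.3 ± 1.0 FPKM (log2 difference −0.64, SE 0.11, limma adjusted p = 0.374). The panel genes Nqo1, Hspa1a and Il1b were too low to be tested. Over all genes limma called 0 of 12026, with a smallest adjusted p = 0.154, and limma-voom called 0. At an unadjusted p under 0.05 limma on all 12 libraries had 933 genes. Uniform p-values would give 601, and other splits of these 6 libraries gave 55 to 302. On the 10 libraries limma called 29 genes, 13 higher and 16 lower, with 3878 at an unadjusted p under 0.05. A replicate block on the 10 libraries gave a far larger count, which is listed with the alternatives below. The count on the 10 libraries thus depends on whether the replicate number is in the model, and an effect shared by replicate number stays open. In 34.1% of the genes every HBSS library lay on one side of every 100 µM library, where chance gives 10% for independent genes. Other splits of these 6 libraries reached 17.5%, and other splits in the remaining HOCl comparisons 28.9% and 30.6%.

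**Figure D2:**
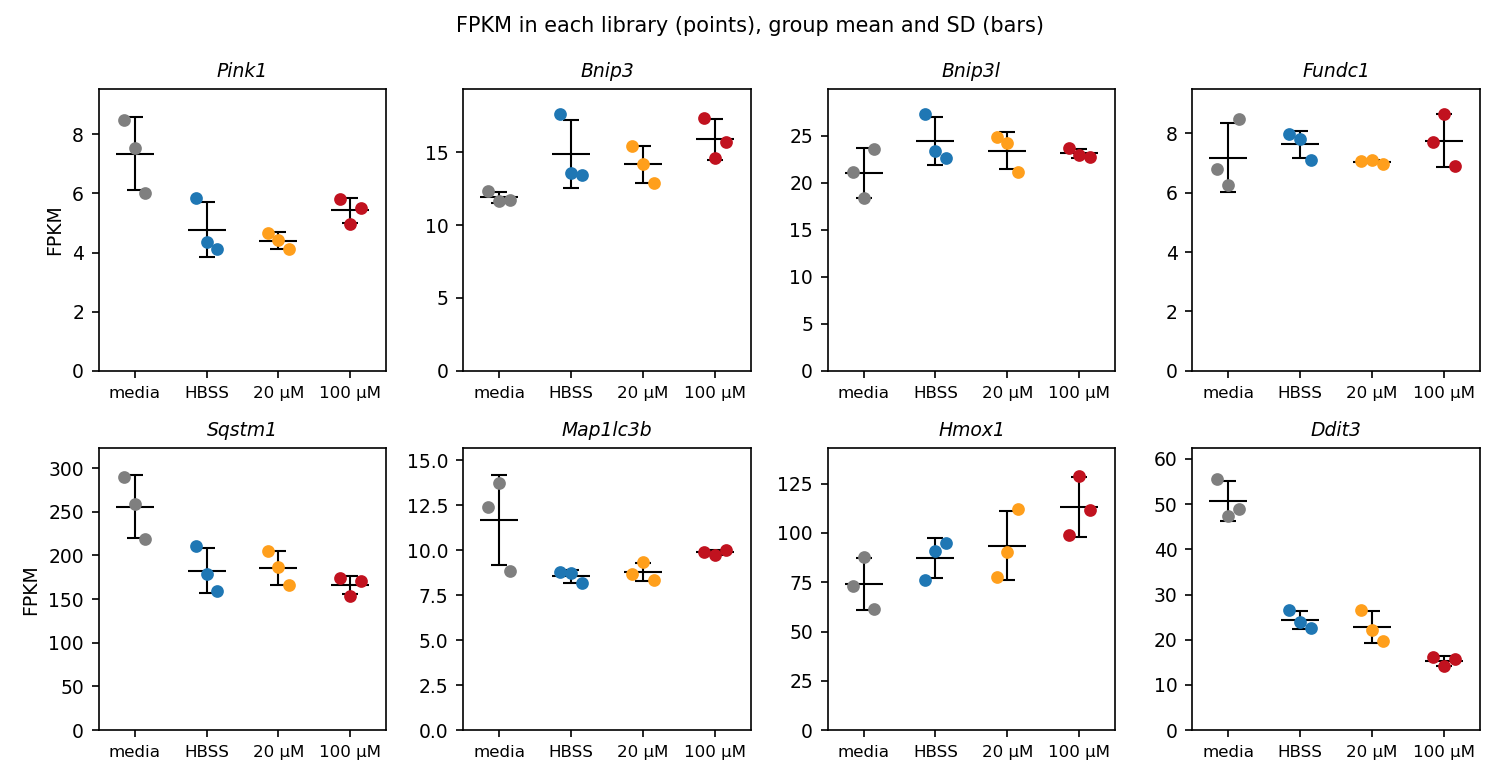
FPKM of 8 panel genes in the 12 libraries, with the group on the horizontal axis and FPKM from 0 on the vertical axis. Points are libraries and bars the group mean and SD (n = 3). Mean Pink1 was 4.78 FPKM in HBSS, 4.41 at 20 µM and 5.42 at 100 µM, while mean Ddit3 was 24.4, 22.8 and 15.3.

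Camera's list test at 100 µM called genes of redox defence, respiration and protein turnover higher and interferon and amino acid stress genes lower, each by a small amount. These calls were lost with an estimated correlation, and 5 of the 10 splits of the 6 libraries, the real one included, called as many lists (real 8, highest other 11). Some of these lists were also higher in cell media replicates 1 and 2, the libraries that stood apart, with means of 0.62 and 0.70 from HBSS for oxidative phosphorylation, 0.83 and 0.85 for ribosomal proteins and 0.43 and 0.58 for antioxidant enzymes. On component 1 the 100 µM libraries (−8.55 to 7.22) lay nearer to these 2 (46.0 and 47.4) than the HBSS libraries did (−16.8 to −9.63). NRF2 targets rose by a median of 0.19, with 19 of 27 higher (camera, adjusted p = 0.000164, and adjusted p = 0.769 with an estimated correlation). With quantile normalization the median was 0.082 (camera, adjusted p = 0.0209, range 5.37e-05 to 0.0209). Prdx1, a peroxiredoxin that removes hydrogen peroxide, stood at 493 ± 22 FPKM in HBSS and 628 ± 53 at 100 µM (log2 difference 0.35, SE 0.10), and Hmox1, the heme oxygenase, at 87.2 ± 10.0 and 113 ± 15. Other NRF2 targets stood lower at 100 µM. The cystine transporter gene Slc7a11, also a member of the ATF4 list described below, was at 7.35 ± 0.27 and 5.98 ± 0.37. The thioredoxin reductase gene Txnrd1 was at 51.2 ± 2.2 and 50.1 ± 1.0, a difference of −0.027. The Txnrd1 difference was 0.0037 with median-of-ratios scaling and 0.0018 without HBSS replicate 3. The list of antioxidant enzymes shares only the catalase gene Cat with the NRF2 list. It was higher in 17 of 18 members with a median of 0.15 (camera, adjusted p = 0.00225, and adjusted p = 0.887 with an estimated correlation). Among them, the superoxide dismutase gene Sod1 stood at 34.3 ± 2.3 and 43.7 ± 4.0. All 51 genes of nuclear-encoded oxidative phosphorylation stood higher, with a median of 0.18 (camera, adjusted p = 1.56e-05, and adjusted p = 0.887 with an estimated correlation), as in Cox7b, a subunit of cytochrome c oxidase, at 119 ± 6 and 136 ± 8. Proteasome genes were higher in 30 of 32 with a median of 0.13 (camera, adjusted p = 5.42e-05, and adjusted p = 0.887 with an estimated correlation). With quantile normalization the median was 0.042 and the call ended (camera, adjusted p = 0.176, range 1.4e-07 to 0.176). Nfe2l1, the factor that drives their transcription, was at 113 ± 12 and 90.5 ± 10.1. Once the trend of each library on exon length was removed, the median of oxidative phosphorylation was 0.11, and with quantile normalization 0.083 (camera, adjusted p = 0.00774 and 0.0101, within a range of 1.07e-13 to 0.0101 over the alternatives).

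ATF4 targets, the genes of amino acid and integrated stress, were lower at 100 µM in 28 of 29 members with a median of −0.18 (camera, adjusted p = 2.39e-05, and adjusted p = 0.887 with an estimated correlation). Besides Ddit3, which was the 1 member called when adjusted over the list alone with all 12 libraries, Chac1, an enzyme that degrades glutathione, stood at 13.4 ± 3.2 FPKM in HBSS and 8.27 ± 1.13 at 100 µM. Interferon-stimulated genes were lower in 22 of 29 with a median of −0.13 (camera, adjusted p = 0.000583, and adjusted p = 0.887 with an estimated correlation). With all 12 libraries in the fit, 2 of them were called when adjusted over the list alone. Oas1g was at 25.9 ± 1.4 and 18.9 ± 1.7 (log2 difference −0.44, SE 0.09), and Oas2 at 5.26 ± 0.39 and 3.05 ± 0.24. DNA replication genes were higher in 30 of 34 with a median of 0.13 (camera, adjusted p = 0.00031), among them the sliding clamp gene Pcna at 216 ± 20 and 265 ± 14, and cytosolic ribosomal proteins in 48 of 50 with a median of 0.12 (camera, adjusted p = 0.0103). Both of these lists had an adjusted p = 0.887 with an estimated correlation in camera. Without HBSS replicate 1 the DNA replication median was 0.031 (camera, adjusted p = 0.192, range 1.01e-05 to 0.192), and that of ATF4 targets was −0.093, or −0.10 without HOCl 100 µM replicate 2. The ribosomal call ended without HBSS replicate 3 (adjusted p = 0.107), without HOCl 100 µM replicate 2 (0.0779), with the exon length trend removed (0.533), with the GC trend removed (0.0574) and with quantile normalization (0.917) in camera, over a range of 2.83e-07 to 0.917. Its median was −0.0025 with quantile normalization. In all, camera called 8 of 31 lists, the same 8 on the 10 libraries, and 0 with an estimated correlation, while the medians of the 23 others ran from −0.058 to 0.22. Over all genes, 0 members of these lists passed limma's test with all 12 libraries. On the 10 libraries the interferon-stimulated genes Oas1g, Oas2, Ifi44 and Ifi203 passed, with limma adjusted p values from 0.0463 to 0.0484.

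**Figure D3:**
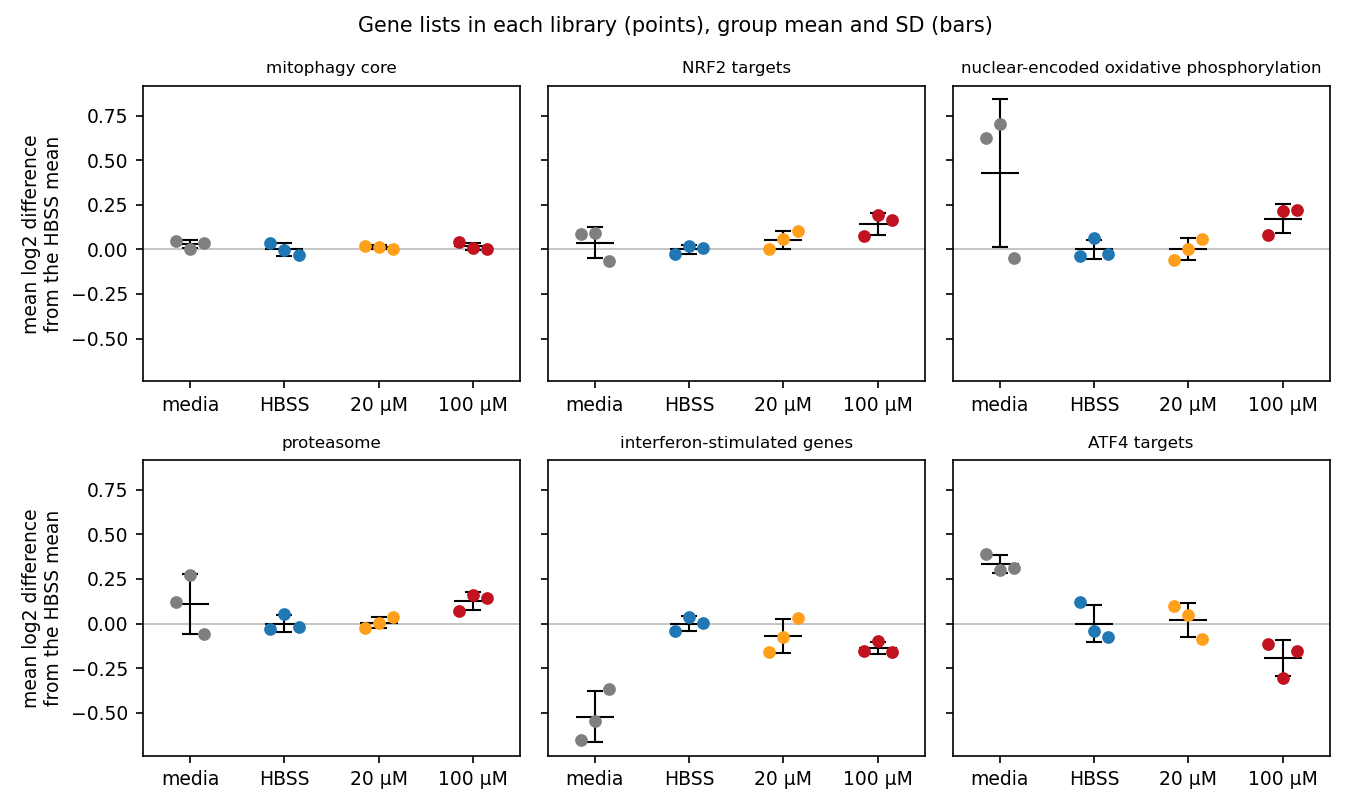
Mean log2 difference from the HBSS mean over the measured members of 6 gene lists, with the group on the horizontal axis and the difference on the vertical axis, shared by all panels. Points are libraries and bars the group mean and SD (n = 3). The mitophagy core lay at 0.011 ± 0.010 at 20 µM and 0.016 ± 0.020 at 100 µM, and ATF4 targets at −0.19 ± 0.10 at 100 µM.

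The comparison of the doses, 100 µM with 20 µM HOCl, uses no HBSS library but shares the 100 µM libraries with the comparison of that dose with HBSS. It showed respiration genes higher and ATF4 targets lower at 100 µM, while several other calls ended with quantile normalization. Oxidative phosphorylation genes were higher at 100 µM in 50 of 51 members with a median of 0.17 (camera, adjusted p = 2.59e-08, and adjusted p = 0.675 with an estimated correlation), and proteasome genes in 31 of 32 with a median of 0.14 (camera, adjusted p = 9.82e-07, and adjusted p = 0.637 with an estimated correlation). Cycs, cytochrome c, stood at 86.7 ± 3.9 FPKM at 20 µM and 101 ± 6 at 100 µM. ATF4 targets were lower in 28 of 29 with a median of −0.21 (camera, adjusted p = 1.82e-07, and adjusted p = 0.637 with an estimated correlation), with Ddit3 at 22.8 ± 3.5 and 15.3 ± 1.0 and Gdf15, a stress-induced cytokine, at 6.08 ± 0.96 and 3.99 ± 0.64. Heat shock genes were higher in 13 of 14 with a median of 0.14, and the chaperone gene Hspa8 stood at 206 ± 42 and 276 ± 52. Its log2 difference of 0.42 ranged from 0.28 to 0.57 with 1 library left out. Macrophage identity genes were higher in 21 of 29 with a median of 0.086. Among them, Lyz2, a lysozyme, stood at 2250 ± 46 and 2716 ± 190. The Lyz2 difference was 0 with quantile normalization. That method sets genes of equal rank to equal values, so the 0 cannot decide whether a gene this high differed. Immediate early genes were lower in 12 of 17 with a median of −0.13, with Jun at 33.4 ± 2.6 and 26.2 ± 0.6. For these last lists camera gave an adjusted p = 0.00511, 0.0188 and 0.0405, and each an adjusted p = 0.675 with an estimated correlation.

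DNA replication (median 0.11), cytosolic ribosomal proteins (0.13), NRF2 targets (0.078) and antioxidant enzymes (0.11) also rose between 20 µM and 100 µM, so camera called 10 of 31 lists, of which 9 were also called on the 10 libraries and 0 with an estimated correlation (lowest adjusted p = 0.637 with an estimated correlation). The mitophagy core had a median of −0.0040 and a mean of 0.0052, with 17 of 38 higher (camera, adjusted p = 0.531), and its median was 0.033 with median-of-ratios scaling. With the exon length trend removed, camera no longer called ribosomal proteins (adjusted p = 0.282, range 1.99e-09 to 0.963), antioxidant enzymes (0.0575, range 0.000137 to 0.153) or macrophage identity (0.153, range 0.00859 to 0.747). With quantile normalization these 3 calls ended too, with medians of 0.0081, 0.083 and 0.016 (camera, adjusted p = 0.963, 0.153 and 0.747). So did those of proteasome genes (0.075), heat shock (0.095) and NRF2 targets (0.045), with a camera adjusted p = 0.0794, 0.282 and 0.21, over ranges of 2.31e-09 to 0.0794, 0.000834 to 0.282 and 0.000614 to 0.21. The oxidative phosphorylation median was then 0.11 (camera, adjusted p = 0.000449, range 3.24e-17 to 0.000449). The immediate early call ended with median-of-ratios scaling (camera, adjusted p = 0.0781), without HOCl 20 µM replicate 3 (0.209), without HOCl 100 µM replicate 1 (0.454) and without cell media replicates 1 and 2 (0.176), over a range of 0.00075 to 0.454. Leaving out 1 library moved other medians: heat shock was 0.078 without HOCl 20 µM replicate 1, 0.22 without HOCl 20 µM replicate 3 and 0.20 without HOCl 100 µM replicate 1, DNA replication 0.054 without HOCl 20 µM replicate 1, NRF2 targets 0.13 without HOCl 20 µM replicate 2 or 3, and macrophage identity 0.057 without HOCl 100 µM replicate 3. With median-of-ratios scaling the medians of NRF2 targets and macrophage identity were 0.12 and 0.13. Of single genes limma called 0 of 12026, with 481 at an unadjusted p under 0.05 (595 in another split of these 6 libraries) and a smallest adjusted p = 0.253, limma-voom called 0, and limma on the 10 libraries called 0. A replicate block on the 10 libraries called far more, as listed with the alternatives below. Here too the count on the 10 libraries depends on whether the replicate number is in the model. Adjusted over the list alone and with all 12 libraries in the fit, 1 of the ATF4 targets passed.

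Whether the doses moved the same genes could not be read from calls, since limma called 0 genes at either dose and 0 in both, where independent lists give 0. Across the 12026 genes, which are not independent replicates, the log2 differences at 20 µM and 100 µM from HBSS correlated at 0.55, against 0.50 in 100 simulations of unchanged groups with the same 3 HBSS libraries. Their covariance was 0.0174 against a simulated 0.0096, a difference of 0.0078, and 64.1% of genes had the same sign against 66.7% simulated. The simulated genes varied independently of each other, while genes of a real library can deviate together. The real values can therefore not be read as an excess over unchanged groups. The 3 controls were too few to split, so part of any difference from the simulation may come from sharing them.

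The comparison of HBSS with cell media asks what the vehicle treatment did by itself, and here 2 single genes passed limma's test. Ddit3 (ENSMUSG00000025408), the CHOP gene, fell from 50.7 ± 4.4 FPKM in cell media to 24.4 ± 2.0 in HBSS (log2 difference −1.02, SE 0.11, limma adjusted p = 0.0284), lower in 3 of 3 libraries. Ifi44 (ENSMUSG00000028037), an interferon-induced gene, rose from 1.71 ± 0.73 to 5.00 ± 0.14 (log2 difference 1.18, SE 0.15, limma adjusted p = 0.0482), higher in 3 of 3. The median of all genes lay at 0.10, and at −0.013 with median-of-ratios scaling and 0.023 with quantile normalization. Relative to that median, Ddit3 stood at −1.13 and Ifi44 at 1.07. These were the 2 of 12026 genes called, 1 higher and 1 lower, with 4806 at an unadjusted p under 0.05. Quantile normalization gave 3 higher and 1 lower, and limma-voom 3 higher and 1 lower. Neither call held without any 1 library except cell media replicate 3: limma's adjusted p for Ddit3 and Ifi44 was 0.15 and 0.15 without cell media replicate 1, 0.101 and 0.199 without cell media replicate 2, 0.097 and 0.109 without HBSS replicate 1, 0.16 and 0.16 without HBSS replicate 2, and 0.191 and 0.191 without HBSS replicate 3. Without cell media replicate 3, limma called 7852 genes, 5120 higher and 2732 lower, and without each of the 5 others 0. On the 10 libraries, with cell media replicate 3 alone in its group (n = 1), it called 0, with 823 at an unadjusted p under 0.05 and adjusted p = 0.372 and 0.194 for these genes, whose ranges over the alternatives were 5.12e-05 to 0.372 and 1.23e-06 to 0.199. The log2 difference there was −0.98 for Ddit3 and 0.76 for Ifi44.

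Interferon-stimulated genes were higher in HBSS in 28 of 29 members, with a median of 0.37 relative to all genes (0.47 before subtraction, and 0.31 on the 10 libraries), and camera called them with an adjusted p = 2.89e-10, or adjusted p = 0.56 with an estimated correlation. Irf7, a transcription factor that amplifies interferon, stood at 4.59 ± 0.12 FPKM in cell media and 7.84 ± 0.57 in HBSS, and Oas2 at 1.86 ± 1.01 and 5.26 ± 0.39. ATF4 targets were lower in 24 of 29 with a median of −0.38 relative to all genes (camera, adjusted p = 1.29e-07, and adjusted p = 0.569 with an estimated correlation), with Nupr1, a stress-induced chromatin factor, at 23.3 ± 4.7 and 12.4 ± 1.6. Histone genes, among them the replication-independent H1f0, were lower in 6 of 6 with a median of −0.55 relative to all genes (camera, adjusted p = 0.00128, and adjusted p = 0.56 with an estimated correlation), with Hist1h1c at 43.2 ± 5.7 and 30.3 ± 2.0. Adjusted over the list alone, 25 interferon-stimulated genes, 13 ATF4 targets and 4 histone genes passed, and 19, 1 and 0 against cell media replicate 3 alone on the 10 libraries. The ATF4 median before subtraction was −0.28, −0.18 without HBSS replicate 3, −0.42 with median-of-ratios scaling and −0.13 with quantile normalization. Mitophagy core genes had a median of −0.028 relative to all genes, 0.073 before subtraction, a mean of −0.030 and a camera adjusted p = 0.428, with 1 higher and 7 lower when adjusted over the list alone, and 0 on the 10 libraries. Pink1 stood at 7.35 ± 1.24 FPKM in cell media and 4.78 ± 0.94 in HBSS, Sqstm1 at 256 ± 36 and 183 ± 26, and Map1lc3a at 15.7 ± 7.2 and 6.09 ± 1.58 (limma adjusted p = 0.0711 for each). Their log2 differences of −0.53, −0.48 and −1.17 were −0.29, −0.27 and −0.45 on the 10 libraries.

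Ribosomal protein genes were lower in HBSS in 47 of 50 with a median of −0.75 relative to all genes, nuclear-encoded oxidative phosphorylation in 46 of 51 with −0.56, and antioxidant enzymes in 16 of 18 with −0.36. Camera gave these an adjusted p = 8.23e-14, 6.34e-12 and 0.000238, and for each an adjusted p = 0.802 with an estimated correlation. Rpl27, a protein of the large ribosomal subunit, stood at 459 ± 170 FPKM in cell media and 244 ± 5 in HBSS, and Uqcrq, a subunit of respiratory complex III, at 167 ± 72 and 75.4 ± 5.6. These are the lists in which cell media replicates 1 and 2 stood apart: without them, against cell media replicate 3 alone, the medians were −0.014 for ribosomal proteins, 0.043 for oxidative phosphorylation and 0.030 for antioxidant enzymes (camera, adjusted p = 0.855, 0.02 and 0.518, over ranges of 2e-19 to 0.855, 6.86e-18 to 0.02 and 2.32e-05 to 0.518). Before subtraction, the oxidative phosphorylation median of −0.45 was −0.71 without cell media replicate 3 and −0.29 with quantile normalization. The ribosomal median of −0.65 was −0.27 with quantile normalization, and the antioxidant median of −0.26 was −0.17 without cell media replicate 2. DNA replication genes were higher in HBSS in 27 of 34 with a median of 0.15 relative to all genes, as were genes of ribosome biogenesis in 24 of 35 with 0.16 (camera, adjusted p = 0.0149 and 0.0476, and for both an adjusted p = 0.802 with an estimated correlation). Mcm10, a replication initiation factor, stood at 7.23 ± 2.07 and 12.4 ± 1.7 FPKM, and Ncl, nucleolin, at 103 ± 23 and 166 ± 19. Camera no longer called these lists without cell media replicate 3 (adjusted p = 0.564 and 0.645), HBSS replicate 2 (0.0907 and 0.0947) or HBSS replicate 3 (0.0691 and 0.099), nor ribosome biogenesis with a pseudocount of 0.1 (0.0536), over ranges of 4.79e-11 to 0.564 and 1.15e-12 to 0.645. Before subtraction the DNA replication median was 0.25, and 0.14 without cell media replicate 1. In all, camera called 8 of 31 lists, 15 against cell media replicate 3 alone on the 10 libraries with 6 in both, and 0 with an estimated correlation, while fry, which compares no list with other genes, called 3, the interferon, ATF4 and histone lists, and 0 in each of the 3 comparisons with HOCl. The medians of the 23 others ran from −0.074 to 0.37.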

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

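The analyses without cell media replicates 1 and 2, with limma-voom, with the exon length or GC trend removed and with these combined, and quantile normalization of lists other than the mitophagy core, were chosen only after the results were seen. The mitophagy core list was called by camera under 0 of its 23 alternatives at either dose, with adjusted p from 0.393 to 0.996 at 20 µM and from 0.347 to 0.917 at 100 µM. Its median at 20 µM reversed with median-of-ratios scaling (−0.0031), quantile normalization (−0.0044) and the GC trend removed (−0.0090), and at 100 µM with quantile normalization (−0.0040) and with the regulators joined to the core (−0.0022). It ranged from −0.0016 to 0.0193 at 20 µM and from −0.0155 to 0.0300 at 100 µM when 1 library was left out. The causes of these reversals were not tested.

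In the HOCl comparisons the counts of genes called by limma moved most with library weights, to 158 at 20 µM and 3401 at 100 µM against HBSS and 6084 between the doses. For HBSS against cell media they gave 7501. The fit of these weights stopped before it converged and gave weights from 0.039 for cell media replicate 3 to 20.597 for HOCl 20 µM replicate 2, so these counts are uncertain. Without a filter the same counts were 6, 1, 11 and 5. With cell media as the control they were 7 at 20 µM and 1052 at 100 µM (716 higher, 336 lower). With only the 2 groups compared they were 2 at 100 µM against HBSS, 1 between the doses and 0 for HBSS against cell media. For HBSS against cell media they were 1 with a pseudocount of 0.5, 1 at a mean of at least 5 FPKM, 4 with quantile normalization, 5 without the mean-variance trend, 4 with limma-voom, 18 with the length trend and 14 with the GC trend removed, and 0 without cell media replicates 1 and 2, which leaves 1 cell media library. Without these 2 libraries 29 genes were called at 100 µM against HBSS, and 26 with the length trend also removed. The causes were not tested, beyond the median standard error of 0.132 with 12 libraries and 0.073 with 10. With 1 library left out, counts ranged from 0 to 1 at 100 µM against HBSS (1 without HBSS replicate 3) and from 0 to 7852 for HBSS against cell media, and were 0 in the other comparisons. The overlap of the doses was 0 in its 5 alternatives.

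No label says what the replicate numbers share. The deviations of 18 pairs with the same number correlated at −0.417 to 0.414, and those of the 9 pairs without cell media at −0.062 to 0.414, with 7 of the 18 above 0.1, and 6 of 12 libraries were closest to a library of their own number. Among HBSS and HOCl libraries, pairs of different numbers from different groups correlated at −0.408 to 0.284. An effect shared by libraries of the same number thus stays open, and the main counts take no account of it. A replicate block gave 193 genes for HBSS against cell media (130 higher, 63 lower) and 0 in the other 3 comparisons. A block without cell media replicates 1 and 2 gave 2979 at 100 µM against HBSS, 2088 between the doses, 0 at 20 µM and 0 for HBSS against cell media.

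Of other lists called, oxidative phosphorylation (0.0426) and antioxidant enzymes (0.0301) reversed for HBSS against cell media replicate 3 alone. Ribosomal proteins at 100 µM reversed with quantile normalization (−0.0025), which also ended the proteasome call at 100 µM and 6 of 10 list calls between the doses. Outside leave-one-out, 170 values of lists were the same and 16 lost their call, and with 1 library left out 150 were the same and 12 lost it. Of single genes, Txnrd1 at 100 µM reversed with median-of-ratios scaling (0.0037), and 531 values were the same, 17 were newly called and 3 lost their call. With 1 library left out 776 were the same, 30 newly called, 10 lost and 12 reversed, with values over ranges at 20 µM of −0.1637 to 0.0446 for Pink1, −0.1214 to 0.0608 for Bnip3, −0.1083 to 0.0217 for Bnip3l and −0.0659 to 0.1363 for Sqstm1, and at 100 µM of −0.1216 to 0.0085 for Bnip3l, −0.1232 to 0.0386 for Atf3, −0.0547 to 0.0903 for Fundc1 and −0.0583 to 0.0018 for Txnrd1. Of the whole panel, 13 of 21 genes at 20 µM and 4 at 100 µM reversed without 1 library. Quantile normalization, run on single genes for direction only, reversed Prdx3, Rpl7 and Rps4x at 100 µM and Gabarapl1 and Txnrd1 at 20 µM, and median-of-ratios scaling also reversed Gabarapl1 at 20 µM (−0.003). Each gene with a range above differed between its groups by less than its standard error.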

Other observations

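In this part, the splits of the 6 libraries within the 10-library analysis, the test of another group's label on cell media replicates 1 and 2, and all single genes named were chosen only after the results were seen.

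Genes outside the fixed rules gave further values for HOCl. Nqo1, a quinone reductase and NRF2 target, was too low to be tested, at 0.33 to 0.49 FPKM in HBSS, 0.46 to 0.63 at 20 µM and 0.82 to 1.00 at 100 µM. Of markers of other cell types, Mmp8, a neutrophil collagenase, stood at 6.33 ± 0.90 FPKM in HBSS, 8.78 ± 0.99 at 20 µM and 8.79 ± 0.80 at 100 µM, and S100a8, a calcium-binding protein of myeloid cells, at 11.4 ± 1.5, 11.2 ± 0.7 and 15.5 ± 1.4. Neither passed limma's test at 100 µM (adjusted p = 0.625 and 0.641). The 29 genes that limma called at 100 µM on the 10 libraries included Gadd45g, a stress-induced growth arrest gene, at 2.46 ± 0.33 and 5.06 ± 0.56 FPKM (log2 difference 0.81), the linker histone gene Hist1h1c at 30.3 ± 2.0 and 41.7 ± 1.9, the cyclooxygenase gene Ptgs1 at 31.5 ± 0.8 and 42.8 ± 1.0, and the macrophage elastase gene Mmp12 at 207 ± 5 and 263 ± 8. Lower at 100 µM were Oas2, Oas1g and Ifi44, the splicing kinase gene Clk1 at 12.2 ± 0.6 and 8.48 ± 0.67, and H2-T23, a nonclassical MHC class I gene, at 7.92 ± 0.29 and 5.68 ± 0.42. On the 10 libraries the limma adjusted p of the 29 genes lay between 0.0463 and 0.05, and with all 12 libraries 0 of them passed, with an adjusted p = 0.154 for Gadd45g.

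The ATF4 and interferon lists lay on a scale that also took in the untreated cells. Relative to the HBSS mean, ATF4 targets stood at 0.33 ± 0.05 in cell media, 0.020 ± 0.096 at 20 µM and −0.19 ± 0.10 at 100 µM, with an SD of 0.10 within HBSS. Interferon-stimulated genes stood at −0.52 ± 0.14 in cell media, −0.068 ± 0.094 at 20 µM and −0.14 ± 0.03 at 100 µM, with an SD of 0.040 within HBSS. So ATF4 targets lay farther from cell media at 100 µM than in HBSS, and interferon-stimulated genes nearer to it. Both sets of differences share the HBSS libraries, and no test of this order was run.

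The 6 libraries of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. As many genes as the real split were called in 10 of 10 splits at 20 µM, at 100 µM and between the doses, where the real split and the highest other gave 0 genes, and in 1 of 10 for HBSS against cell media, where the real split gave 2 genes and the highest other 0. As many lists were called in 10 of 10 splits at 20 µM (real 1, highest other 11), 5 at 100 µM (real 8, highest other 11), 4 between the doses (real 10, highest other 15) and 5 for HBSS against cell media (real 8, highest other 13), so splits that mix the groups, 2 libraries of one with 1 of the other, also call as many lists or more. In each HOCl comparison the mixed split with the most lists put both replicate 1 libraries together. Its count may therefore include an effect shared by replicate number, which was not tested. On the 10 libraries, 100 µM against HBSS gave 29 genes and the highest other split 0, and 3878 genes at an unadjusted p under 0.05 against 2231, while lists gave 8 against 12. In the other HOCl comparisons another split gave more: 2020 genes at an unadjusted p under 0.05 against 371 at 20 µM, and 3377 against 3156 between the doses, where it called 1 gene and the real split 0.

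The first pattern weighed is the higher level of energy, translation and protein turnover genes at 100 µM than in HBSS. GC content as the whole cause is argued against, since the pooled median of the oxidative phosphorylation, ribosomal protein, proteasome and antioxidant lists kept 98.6% of its size with the GC trend removed (0.147 before, 0.145 after). Exon length stays open, with 70.7% kept (0.104 after), and the slope of expression on length differed between the groups, at 0.098 ± 0.035 in HBSS and −0.029 ± 0.029 at 100 µM. Normalization stays open for part of it, since the proteasome and ribosomal medians were 0.042 and −0.0025 with quantile normalization and neither was called. A difference of the kind that set cell media replicates 1 and 2 apart stays open, since oxidative phosphorylation, ribosomal and antioxidant genes were higher in those 2 libraries as well. A library effect also stays open, since other splits gave up to 11 called lists. HOCl itself is the biological explanation the design offers, and it may account for the rest.

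The second pattern is the rise of NRF2 targets with the fall of interferon-stimulated genes at 100 µM. The median difference between the lists, 0.32, kept 102.6% of its size with the length trend removed and 98.5% with the GC trend removed, which argues against both as the whole cause. Normalization stays open for part of the NRF2 difference, since its median of 0.19 was 0.082 with quantile normalization. A library effect stays open too, since other splits gave up to 11 called lists. Cell media replicates 1 and 2, given no HOCl, had NRF2 targets at 0.085 and 0.091 from the HBSS mean. Their interferon-stimulated genes stood at −0.65 and −0.55. Cell media replicate 3 stood at −0.064 and −0.37 for these lists. A difference of the kind that set replicates 1 and 2 apart thus stays open. A candidate explanation, not tested here, is a lasting oxidant response 24 h after HOCl. These libraries cannot separate it from a shared difference between the 3 HBSS and 3 HOCl 100 µM libraries.

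The third pattern is the distance of cell media replicates 1 and 2 from the other 10 libraries. Against the label of another group in this series, their ATF4 targets stood at 0.303 or more above the HBSS mean, as did those of cell media replicate 3 at 0.309, while the highest of the 9 HBSS and HOCl libraries was 0.119. Against reads from another cell type, 0 of 47 measured markers stood at 1 FPKM or more and at least 2 times above the other libraries in both. The cell media treatment itself was not tested apart from the pattern and stays open, although replicate 3, given the same treatment, stood with the other libraries. A difference in RNA or library preparation stays open as a possible explanation, since exon length accounted for 20.8% of the variance of the difference and small RNA genes were among the lowest in both libraries, and so does the unlabelled sequencing instrument, which was not tested.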
